A study of Mus musculus with 27 samples.

How the data were processed

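RNA from mouse hearts was measured on 27 whole-transcript expression arrays. Per the labels' protocols, C57Bl/6J male littermates of 10 to 12 weeks had sham surgery or transverse aortic constriction (TAC) and received vehicle or JQ1 by injection from 1.5 days after surgery. Hearts were taken at days 3, 11 and 28, RNA came from 10 to 20 mg of tissue, and the Ambion WT Expression Kit with Affymetrix labelling was used. The labels give 9 groups of 3 arrays: sham vehicle, TAC vehicle and TAC JQ1 at each day. The values deposited by the authors are log2 signal values of 34760 probe sets per array, with none missing and a range of 1.67 to 14.2. The normalization is not given in the sources used here. Array medians lay between 6.954 and 7.043, and the values were used as deposited. The submitters' processing notes name limma, with no version, for their own comparisons.

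Of the probe sets 22961 were named with a gene and 21640 of these with 1 gene. A further 1321 listed several genes and 11799 listed none, and both kinds were left out of the gene tests and tested apart. Of the probe sets with 1 gene 21553 had an Entrez identifier found in the reference, and 0 symbols were changed by it. For 954 genes with more than 1 probe set the probe set with the highest mean over the 27 arrays was used, which left 19937 genes. No coordinates are given, because the reference annotation (GRCm38.p6) lists genomic positions of genes and not of probes.

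One linear model with a mean for each of the 9 groups was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8). It had 18 residual and 4.9 prior degrees of freedom. Within each day TAC vehicle was compared with sham vehicle and TAC JQ1 with TAC vehicle. The mean of the 3 days was compared for these and for TAC JQ1 with sham. Moderated F tests asked whether the TAC effect, the JQ1 effect or the sham level differed between days. The p-values were adjusted by the Benjamini-Hochberg method over the 19937 genes of each comparison, and genes with adjusted p under 0.05 were called. Counts at 1.5-fold or more are given beside them. Standard errors are those of the moderated fit. The median residual SD of a gene was 0.125.

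Gene lists, 35 in all, were written from general knowledge before the data were examined, as were the groups, the comparisons and the alternatives. They cover cardiomyocyte stress and sarcomere genes, calcium handling, matrix, growth signalling, inflammation, cell cycle, fuel metabolism, protein folding, the clock, known targets of BET inhibition and markers of other cells of the heart. Of 857 names listed once 776 were matched. Each list was tested with camera of limma, with an inter-gene correlation of 0.01 and again with an estimated correlation, and with fry, adjusted over the 35 lists of a comparison. For each list the members called over all genes are given first, and then in brackets those called when adjusted over the list alone. Whether JQ1 opposed TAC was tested with fry and camera on the 200 genes with the highest and the 200 with the lowest moderated t for TAC on the other days, so that the choice and the test shared no array, with p adjusted over the 6 sets. Simulated data without effects, in 100 draws, gave the correlation and covariance that the shared TAC vehicle arrays alone would produce.

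Genes named in the text were chosen by a rule fixed beforehand. The rule takes a fixed set of genes of hypertrophy, fibrosis and BET inhibition, the 6 largest changes per direction among called genes with no overlap between groups, and up to 4 members per list with the smallest p (2 where none was called). It also takes the 6 genes per day with the largest TAC effect and an opposite JQ1 call, the 6 smallest p per test between days and the 6 smallest p per direction of each mean over days. Some genes of the fixed set are not reported here. The 9 macrophage markers described singly in the closing section were chosen by level after the list was seen to fall.

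The tests were first run on simulated data with 200 planted genes. For TAC at day 11 planted changes of 1.2, 1.5, 2 and 4-fold were found in 14%, 74%, 100% and 98% of cases, with 10 of 153 called genes not planted. For JQ1 at day 11 the shares were 14%, 80%, 98% and 100% (12 of 158 not planted), and for the TAC effect by day 2%, 46%, 90% and 98% (8 of 126). Of the 35 lists 1 was called, the planted one. Without an effect the medians of the opposition test lay between −0.02 and 0.03 and the lowest fry p was 0.0569. Genes were drawn independently of each other, so these simulations do not show how the tests behave with correlated genes.

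Alternatives were quantile normalization of the values again, centring each array on its median, leaving out the dimmest genes (1 in 3 by mean level), the mean of a gene's probe sets, eBayes with trend and robust options, and array weights. Array weights used the gene-by-gene method, because the default method did not converge. Further alternatives were a block for the replicate number within day, a fit to only the 2 groups compared, a 1.5-fold threshold and leaving out each array in turn. Leaving out arrays in the tests between days and the interquartile range of each array as a covariate were added after seeing the data. Correlation between arrays ranged from 0.9626 to 0.994, and none were identical. JQ1 replicate 1 of day 3 stood apart most (median correlation 0.9747, array weight 0.215) and was kept. Tables and plots were made with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.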

Results

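Transverse aortic constriction (TAC) raises the pressure against which the heart pumps, and the deposited arrays profile mouse hearts 3, 11 and 28 days after it. Each day has 3 groups of 3 arrays: sham surgery with vehicle, TAC with vehicle, and TAC with the BET bromodomain inhibitor JQ1. JQ1 keeps bromodomain proteins off acetylated chromatin. Expression of 19937 genes was compared on the log2 scale, with 1 moderated fit (limma) to the 27 arrays. Values below are log2 fold changes ± standard error with Benjamini-Hochberg adjusted p over all genes, and every within-day comparison has n = 3 arrays per group. Per the labels the mice were male littermates, and nothing else in the labels says that the arrays come from separate animals. The p-values then measure only the spread between these samples. That spread is 1 value per gene pooled over the 9 groups, and not the spread of the arrays of a single day. Day 3 counts fell most when only the 2 groups compared were fitted (TAC from 1506 to 250, JQ1 from 2372 to 422). No group in the labels had sham surgery with JQ1, so every JQ1 effect here is an effect in hearts with TAC.

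At day 3 the largest rises with TAC included matrix genes. Timp1, an inhibitor of matrix metalloproteinases, went from a mean level of 7.23 in sham hearts to 11.23 (SE of the difference 0.37, adjusted p = 1.35e-06). The matricellular genes Postn (2.30 ± 0.24), Thbs1 (2.26 ± 0.26) and Tnc also rose. So did the collagen crosslinking enzyme Lox (2.43 ± 0.38) and the retinoic acid enzyme Aldh1a2 (2.49 ± 0.36). Cardiomyocyte stress genes rose with them: the natriuretic peptides Nppb (2.21 ± 0.32, adjusted p = 0.000151) and Nppa (1.44 ± 0.18), the slow myosin heavy chain Myh7 (1.94 ± 0.22), skeletal actin Acta1 (1.44 ± 0.29) and the stretch-responsive Ankrd1 (0.77 ± 0.07). The profibrotic genes Ccn2 (1.54 ± 0.19), Tgfb2 (0.91 ± 0.16) and Col1a1 (0.89 ± 0.15) and the cytokine Il6 (1.27 ± 0.20) rose too. Genes that fell included the mitochondrial uncoupling protein gene Ucp3 (−1.71 ± 0.30), the carboxylesterase Ces1d (−1.27 ± 0.25), the unannotated A530016L24Rik (−1.21 ± 0.20), the hydrolase Cmbl (−1.11 ± 0.14) and the potassium channel subunit Kcnv2 (−1.02 ± 0.12). Without TAC vehicle replicate 2 the falls of Inmt (−1.90) and Mylk4 (−1.08) were not called (adjusted p = 0.0754 and 0.133). The rise of Myc (0.75 ± 0.16, adjusted p = 0.00398) was lost without the same array (adjusted p = 0.0544). Myh6, the calcium pump gene Atp2a2 and Hexim1 were not called (adjusted p = 0.741, 0.54 and 0.846).

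Among gene groups at day 3, proliferation, stress and matrix genes rose. Of 37 proliferation genes 26 rose and none fell, 32 when adjusted over the list alone, with a median of 0.69 (camera adjusted p = 4.29e-33, and 0.0366 with an estimated correlation). Mki67 (1.62 ± 0.22) and Top2a (1.57) are examples. TAC vehicle replicate 2 had a mean score of 0.857 on this list against 0.13 and 0.259 in the other two. Fetal and stress genes of cardiomyocytes, which mark the hypertrophic response, rose in 18 of 25 (20 over the list alone, adjusted p = 0.00177 with an estimated correlation). Collagens rose in 9 of 19 (12 over the list alone), other matrix genes in 19 of 40 (26 and 2 lower), TGF-beta targets in 8 of 21 (12) and macrophage markers in 8 of 25 (16), among them Col3a1 (1.13), Fn1 (1.63) and Cd68 (1.03 ± 0.15). All of these stayed called with an estimated correlation, at adjusted p = 0.0366, 0.0326, 0.0191 and 0.0366. Immediate early genes such as Btg2 (0.79) and Ier3 (0.69) rose in 5 of 26 (14 over the list alone, adjusted p = 0.0326 with an estimated correlation), and genes of the unfolded protein response such as Edem1 (0.58) in 8 of 24 against 1 that fell (14 and 2, adjusted p = 0.0366). Fuel genes moved the other way. Fatty acid uptake and oxidation fell in 17 of 33 (22 over the list alone, median −0.29), as in Etfa (−0.45), Hadh (−0.40) and Acaa2 (−0.40), but with an estimated correlation adjusted p = 0.0689. Genes of the tricarboxylic acid cycle fell in 7 of 22 (13) and respiratory chain subunits in 5 of 61 (15), with adjusted p = 0.0873 and 0.152 with an estimated correlation.

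A further 3 groups were called at day 3 with TAC, none of them kept with an estimated correlation. Cytokines and NF-kappaB targets rose in 7 of 35 (11 over the list alone, adjusted p = 1.19e-06, and 0.202 with an estimated correlation), with Ptgs2 at 1.27. Lcn2, a gene of the neutrophil list and not of this one, was at 2.24. Cytosolic ribosomal protein genes rose in 4 of 30 (6, adjusted p = 5.47e-07, and 0.166 with an estimated correlation), with a mean shift of 0.13 that was 0.08 without TAC vehicle replicate 2. Calcium handling genes and ion channels fell in 9 of 30 and rose in 1 (10 and 3), for example Hcn2 (−0.50), Kcnj5 (−0.38) and, upward, the sodium-calcium exchanger Slc8a1 (0.57). That group had adjusted p = 0.00668, but 0.34 with an estimated correlation and 0.0645 without TAC vehicle replicate 2, where its mean shift went from −0.17 to −0.10. Markers of endothelial cells, neutrophils and fibroblasts were not called as groups. Endothelial markers had 0 called by limma (3 at an unadjusted p under 0.05) with a median of −0.08, neutrophil markers had 1 and fibroblast markers had 5 higher and 2 lower.

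Day 3 gave 1506 genes called, 842 higher and 664 lower, and of those changed at least 1.5-fold 290 were higher and 67 lower. Non-overlapping groups were seen in 4298 genes, or 21.6% against 10% by chance, and 1446 of the called genes were among them. The number called was the least steady of the TAC comparisons: 849 without sham replicate 3 and 466 without TAC vehicle replicate 2. With only the 2 groups compared it was 250, 179 higher and 71 lower.

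At day 11 matrix genes made up most of the largest rises. Postn, a fibroblast product of healing tissue, rose by 3.35 ± 0.24 (10.2-fold, adjusted p = 3.89e-09), with Timp1 (3.30 ± 0.37), Thbs4 (2.83 ± 0.35), Acta1 (2.61 ± 0.29), the short-chain collagen Col8a1 (2.50 ± 0.16) and the matrix gene Cilp (2.49 ± 0.28) after it. Nppa (1.82 ± 0.18), Myh7 (1.81 ± 0.22), Nppb (1.49 ± 0.32), Ccn2 (1.53 ± 0.19), Tgfb2 (1.39 ± 0.16), Col1a1 (1.27 ± 0.15) and Ankrd1 (0.84 ± 0.07) remained high. The largest falls were in Ces1d (−1.94 ± 0.25), the opioid precursor Penk (−1.90 ± 0.22), Inmt (−1.85 ± 0.43), Lgals4 (−1.72), the alternative-activation gene Retnla (−1.71) and the phosphorylase kinase subunit Phkg1 (−1.66 ± 0.12). Atp2a2 fell by 0.18 ± 0.05 (adjusted p = 0.0238), a call lost without TAC vehicle replicate 2 (adjusted p = 0.0692), TAC vehicle replicate 3 (0.0799), or sham replicate 1 (0.0682), 2 (0.0524) or 3 (0.0736). Il6, Myc, Myh6 and Hexim1 were not called (adjusted p = 0.348, 0.365, 0.139 and 0.867).

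Matrix groups rose and fuel groups fell at day 11. Of 40 matrix genes other than collagens 32 rose and 1 fell (34 and 1 over the list alone), and of 19 collagens 15 rose (16), with medians of 0.94 and 0.95 and adjusted p = 0.0164 for both with an estimated correlation. Bgn (1.05), Sparc (1.07) and Fbln2 (1.05) are among them. TGF-beta targets (14 of 21 higher, 15 over the list alone) and fetal and stress genes (17 of 25, 19 and 1 lower) had the same adjusted p of 0.0164, with Fstl1 at 1.91, Uck2 at 1.83 and Xirp2 at 1.24. Fibroblast markers such as Meox1 (1.55) and Pi16 (0.97) rose in 10 of 18 and fell in 1 (12 and 2), and macrophage markers such as Mpeg1 (1.04) and Lyz2 (0.79) rose in 16 of 25 (19), with adjusted p = 0.0486 for each with an estimated correlation. Fatty acid genes fell in 28 of 33 (28), including Slc27a1 (−1.08), Ech1 (−0.75) and the coactivator Ppargc1a (−0.72). Genes of the tricarboxylic acid cycle fell in 13 of 22 (18), respiratory chain subunits in 26 of 61 (37), calcium handling and ion channels in 15 of 30 (17 and 2 higher) and clock genes in 8 of 16 (9 and 1 higher). With an estimated correlation these had adjusted p = 0.028, 0.0486, 0.0427, 0.0325 and 0.0292. Pcx (−0.62), Atp5k (−0.53), Kcnj3 (−1.23), Kcnh2 (−0.68), Ciart (−1.23) and Hlf (−0.88) are examples.

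Other groups were called at day 11 only with the fixed correlation. Proliferation genes rose in 27 of 37 and fell in 1 (32 and 1 over the list alone, adjusted p = 1.24e-18, and 0.0904 with an estimated correlation), Mki67 by 1.57. Interferon-stimulated genes such as Cxcl10 (0.57) and Ddx58 (0.55) rose in 8 of 23 (12, adjusted p = 7.71e-07, and 0.355 with an estimated correlation). The unfolded protein response fell in 9 of 24 and rose in 2 (11 and 2, adjusted p = 0.000915, and 0.213 with an estimated correlation), with Herpud1 at −1.05, Dnajb9 at −0.71 and Manf at −0.59. Sham hearts of day 11 scored 0.141 on this list, against −0.0962 and −0.0421 at days 3 and 28, and TAC hearts of day 11 scored −0.0313, so the fall rests on a high sham level. Endothelial markers rose in 6 of 22 (6 and 1 lower, adjusted p = 0.017, and 0.359 with an estimated correlation). Mesothelial markers rose in 3 of 15 (4, adjusted p = 0.0307, and 0.355 with an estimated correlation), a call lost without TAC vehicle replicate 2 (0.0631) or sham replicate 3 (0.0968). In all, 3097 genes were called, 1555 higher and 1542 lower (474 and 285 at 1.5-fold or more), or 1246 and 1733 with arrays centred on their median. The lower genes were also the more numerous without sham replicate 1 (1084 and 1092) or 2 (1238 and 1417) or TAC vehicle replicate 3 (1111 and 1238). Of all genes 6658 had non-overlapping groups, 33.4% against 10% by chance.

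Fibrosis genes and macrophage markers were among the high groups at day 28, when ion channel genes had fallen. Thbs4 (3.00 ± 0.35, 7.99-fold), Postn (2.76 ± 0.24), Timp1 (2.72 ± 0.37), Cilp (2.68 ± 0.28), the NADPH oxidase Nox4 (2.56 ± 0.30) and the acute phase gene Serpina3n (2.48 ± 0.35) rose most. Myh7 (1.87 ± 0.22), Nppa (1.69 ± 0.18), Nppb (1.65 ± 0.32), Acta1 (1.62 ± 0.29), Ccn2 (1.61 ± 0.19), Tgfb2 (0.87 ± 0.16), Col1a1 (0.79 ± 0.15) and Ankrd1 (0.56 ± 0.07) were still high. Ces1d (−1.53 ± 0.25), the myosin kinase Mylk4 (−1.48 ± 0.26), the sodium channel subunit Scn4b (−1.42 ± 0.19), Kcnv2 (−1.15 ± 0.12), Phkg1 (−1.15 ± 0.12) and Zbtb16 (−1.13) fell most, and the adult myosin Myh6 fell by 0.26 ± 0.05 (adjusted p = 0.000596). The fall in Atp2a2 (−0.19 ± 0.05, adjusted p = 0.0144) was lost without TAC vehicle replicate 3 (0.0999) or sham replicate 3 (0.0601). The rise in Il6 (0.62 ± 0.20, adjusted p = 0.0392) was lost without TAC vehicle replicate 3 (0.39, adjusted p = 0.301) or sham replicate 1 (adjusted p = 0.087) or 3 (0.16). The rise in Myc (0.55 ± 0.16, adjusted p = 0.0188) was lost without TAC vehicle replicate 2 (0.086) or 3 (0.0692) or sham replicate 2 (0.0863). Hexim1 was not called (adjusted p = 0.548).

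With an estimated correlation 5 groups were called at day 28. Matrix genes other than collagens rose in 30 of 40 (32 and 1 lower over the list alone, adjusted p = 0.00893), fibroblast markers in 14 of 18 (14 and 1, adjusted p = 0.00893), macrophage markers in 19 of 25 (22, adjusted p = 0.00935) and TGF-beta targets in 12 of 21 (14, adjusted p = 0.0204), with Mfap5 (2.46), Loxl1 (1.36), Ccn5 (1.39), C1qc (1.29), Lyz2 (1.12) and Fstl1 (1.58). On the list of matrix genes other than collagens TAC vehicle replicate 2 had a mean score of 0.209, against 0.758 and 0.905 in replicates 1 and 3. Calcium handling and ion channel genes fell in 16 of 30 (20 and 1 higher, adjusted p = 0.0436), including Kcnj3 (−1.05), Kcnj5 (−0.73) and Kcnj11 (−0.54). Collagens rose in 11 of 19 (12), ribosomal protein genes in 15 of 30 (16) and fetal and stress genes in 10 of 25 (12 and 1 lower), with Col14a1 at 1.62 and Rps20 at 0.46. Fatty acid genes fell in 24 of 33 (26) and those of the tricarboxylic acid cycle in 17 of 22 (17), with Decr1 at −0.44 and Sdha at −0.41. These 5 had adjusted p = 0.089, 0.089, 0.0835, 0.089 and 0.0835 with an estimated correlation.

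Respiratory chain subunits, called with adjusted p = 0.000769 (0.515 with an estimated correlation), fell in 15 of 61 and rose in 1 (17 and 1 over the list alone), Ndufs1 by −0.43. Proliferation genes rose in 7 of 37 and fell in 1 (16 and 1, adjusted p = 6.96e-07, and 0.475 with an estimated correlation). Cytokines rose in 7 of 35 (8, adjusted p = 0.000109, and 0.415 with an estimated correlation), Ccl8 by 1.47 and Cxcl16 by 1.02, interferon-stimulated genes in 2 of 23 (1, adjusted p = 1.81e-05, and 0.475) and immediate early genes in 4 of 26 (4, adjusted p = 0.00164, and 0.255). The mean shift of the immediate early genes, 0.18, was 0.11 without sham replicate 1. Endothelial markers had 1 higher and 1 lower of 22 with a median of 0.15 (adjusted p = 0.013, and 0.47 with an estimated correlation). This was lost without TAC vehicle replicate 2 (0.211) or sham replicate 1 (0.0928), and their mean shift of 0.10 was 0.05 without TAC vehicle replicate 2 and 0.16 without replicate 3. Day 28 had 3013 genes called, 1621 higher and 1392 lower (556 and 113 at 1.5-fold or more), and 1794 without TAC vehicle replicate 3. With arrays centred on their median the split was 1348 higher and 1739 lower, and with quantile normalization again 1538 and 1802. Groups did not overlap in 7516 genes, 37.7% against 10% by chance.

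**Figure D1:**
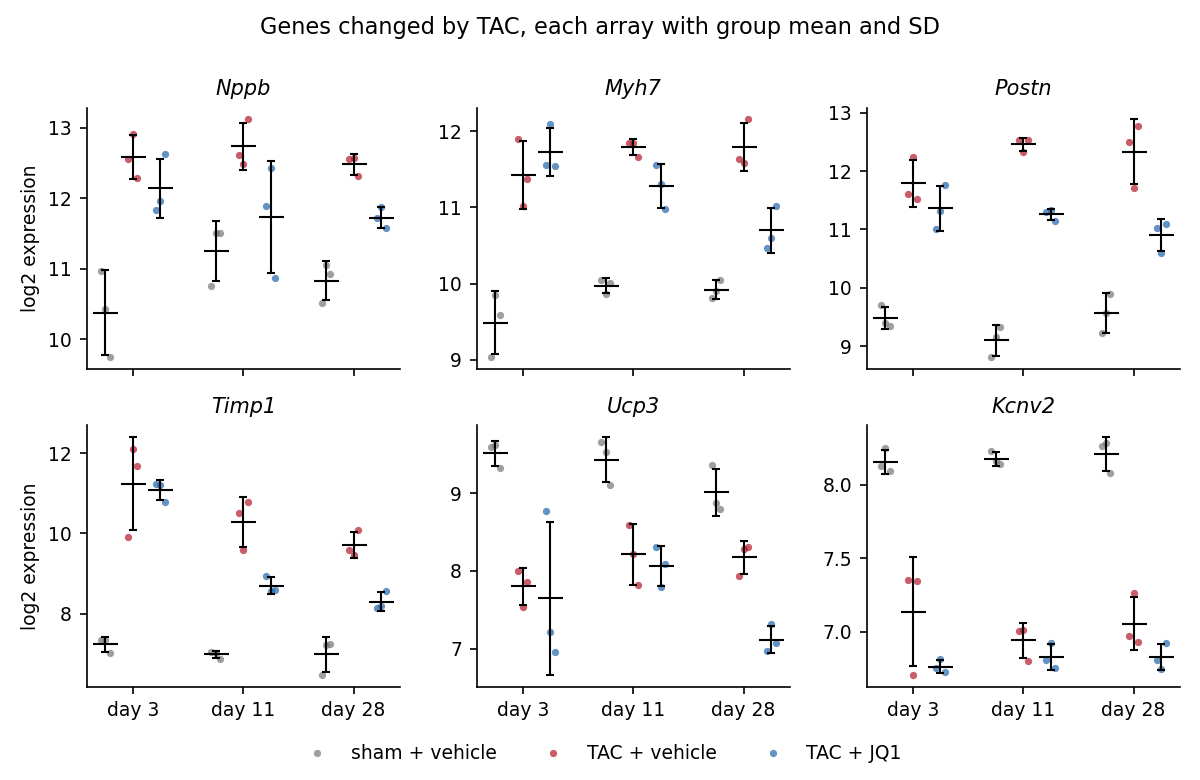
Log2 levels of Nppb, Myh7, Postn, Timp1, Ucp3 and Kcnv2 in sham vehicle, TAC vehicle and TAC JQ1 hearts at days 3, 11 and 28. Each point is 1 array, with n = 3 per group.

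JQ1 at day 3 raised Hexim1 and lowered several myeloid genes, while the main stress genes were not called. Hexim1, which holds the elongation factor P-TEFb inactive, went from 7.46 to 9.31, a rise of 1.85 ± 0.12 (3.61-fold, adjusted p = 4.65e-09). Mir1a-2 (1.90 ± 0.41), Peg3 (1.56 ± 0.35), Mir1a-1 (1.53), Pnmt (1.35 ± 0.23), the glutathione synthesis gene Gclc (1.13 ± 0.10) and Brd2 (1.01 ± 0.08) also rose. Without JQ1 replicate 1 the log2 rise of Mir1a-2 was 1.58 times smaller (adjusted p = 0.0311) and Peg3 was at 0.79. The C-type lectin receptor Clec4a1 (−2.36 ± 0.24), the monocyte chemokine receptor Ccr2 (−2.33 ± 0.34), Clec12a (−2.17 ± 0.27), Itgb6 (−2.07 ± 0.20), the toll-like receptor relative Cd180 (−1.95 ± 0.17) and Fcrls (−1.86) fell most, and Il6 fell by 0.92 ± 0.20 (adjusted p = 0.00403). Nppa (−0.21 ± 0.18, adjusted p = 0.594), Nppb (−0.44 ± 0.32, adjusted p = 0.465), Myh7 (0.30 ± 0.22, adjusted p = 0.469), Acta1 (−0.03 ± 0.29, adjusted p = 0.981), Ankrd1 (−0.12 ± 0.07, adjusted p = 0.355), Postn (−0.43 ± 0.24, adjusted p = 0.295) and Ccn2 (−0.11 ± 0.19, adjusted p = 0.832) were not called. Nor were Myc, Myh6 and Atp2a2 (adjusted p = 0.855, 0.906 and 0.986). Col1a1 (−0.46 ± 0.15, adjusted p = 0.046) was lost without JQ1 replicate 1 (−0.26, adjusted p = 0.321) or 2 (adjusted p = 0.0555) or vehicle replicate 2 (0.284) or 3 (0.0812). Tgfb2 (−0.58 ± 0.16, adjusted p = 0.022) was lost without JQ1 replicate 2 (adjusted p = 0.107) or vehicle replicate 2 (−0.28, adjusted p = 0.193).

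Of the gene groups, 16 were called with JQ1 at day 3 and camera called 0 with an estimated correlation (6 at an unadjusted p under 0.05), while fry called 12. Macrophage and monocyte markers fell in 15 of 25 (16 and 1 higher over the list alone, adjusted p = 7.33e-12, and 0.123 with an estimated correlation), with Ms4a7 at −1.73 and Mpeg1 at −1.45. Proliferation genes fell in 21 of 37 (27, adjusted p = 1.08e-17, and 0.203 with an estimated correlation), among them Mki67 (−1.44 ± 0.22) and Ccna2 (−1.32), which had risen with TAC. The mean shift of the proliferation list, −0.61, was −0.39 without vehicle replicate 2, which stood apart. Interferon-stimulated genes fell in 9 of 23 (16, adjusted p = 7.14e-08, and 0.374 with an estimated correlation), Ifit3 by −1.63 and Oasl2 by −1.30, and cytokines in 13 of 35 (14 and 2 higher, adjusted p = 8.91e-06, and 0.342), Il33 by −1.30 and Cxcl16 by −1.09. Angiogenic and growth factor ligands such as Fgf16 (−0.99) and Igf1 (−0.90) fell in 8 of 27 and rose in 1 (8 and 1, adjusted p = 0.000112, and 0.123 with an estimated correlation). BET and P-TEFb genes rose in 7 of 17 and fell in 1 (10 and 1, adjusted p = 3.98e-06, and 0.135 with an estimated correlation), histone genes (a list that also holds Serpini1) in 3 of 9 (6, adjusted p = 0.000415, and 0.123) and immediate early genes in 5 of 26 (11, adjusted p = 0.000116, and 0.203). Mepce (0.55), H1f2 (0.77), Atf3 (1.17) and Jund (0.65) are examples, and Atf3 was at 0.66 without JQ1 replicate 3 as Fgf16 was at −0.59 without JQ1 replicate 1. Collagens fell in 5 of 19 (8, adjusted p = 0.000306, and 0.442 with an estimated correlation) and other matrix genes in 7 of 40 (10, adjusted p = 5.08e-05, and 0.442), Emilin1 by −0.64. Tgfbi, a gene of the TGF-beta list, which was not called here, was at −0.98. The mean shift of the collagens, −0.30, was −0.16 without JQ1 replicate 1, and the calls of Col1a1, Col1a2, Col3a1, Col14a1 and Col15a1 were lost without it (adjusted p = 0.321, 0.122, 0.0807, 0.0601 and 0.0941). Endothelial markers had 3 lower, smooth muscle and pericyte markers 0 by limma (4 at an unadjusted p under 0.05), and fetal and stress genes 3 higher and 1 lower with a median of −0.06.

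A further 6 groups were called at day 3 with JQ1 in ways that rested on single arrays. Fibroblast markers fell in 5 of 18 and rose in 1 (7 and 1 over the list alone, adjusted p = 0.048, and 0.513 with an estimated correlation), lost without JQ1 replicate 2 (0.078) or 3 (0.0922) or vehicle replicate 1 (0.153) or 3 (0.0693). Calcium handling genes fell in 7 of 30 (8, adjusted p = 0.0152, and 0.513 with an estimated correlation), Kcnj5 by −0.77, lost without JQ1 replicate 3 (0.0508) or vehicle replicate 1 (0.112) or 3 (0.0888). Their mean shift of −0.13 was −0.08 without JQ1 replicate 1 and −0.20 without vehicle replicate 2. Fatty acid genes had 2 higher and 1 lower of 33 (4 and 1, adjusted p = 0.000539, and 0.513 with an estimated correlation), lost without JQ1 replicate 1 (0.176) or vehicle replicate 2 (0.0838). Their mean shift of 0.13 was 0.03 and 0.07 without these 2 arrays and 0.21 without JQ1 replicate 3. Oxidative stress genes (4 of 17 higher, 5 over the list alone, adjusted p = 8.86e-05, and 0.342 with an estimated correlation) had Mt1 at 0.79, and were lost without JQ1 replicate 1 (0.0967), where their mean shift went from 0.35 to 0.14. Glucocorticoid-responsive genes (3 of 15 higher, 5, adjusted p = 0.00218, and 0.513 with an estimated correlation) were lost without the same array (0.415). Their mean shift of 0.38 was 0.10 without it and 0.67 without JQ1 replicate 3. Clock genes (4 of 16 higher, 5, adjusted p = 0.0289, and 0.342 with an estimated correlation) had Cry2 at 0.70 (0.45 without JQ1 replicate 1) and Cry1 at 0.69, and were lost without JQ1 replicate 1 (0.0737) or vehicle replicate 3 (0.139).

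JQ1 at day 3 changed 2372 genes, 854 higher and 1518 lower, and at 1.5-fold or more 81 higher and 453 lower. With arrays centred on their median the split was 1224 higher and 1042 lower. The count was 1485 without vehicle replicate 2 and 1409 without JQ1 replicate 1. With only the 2 groups compared it was 422, 89 higher and 333 lower. Groups did not overlap in 4601 genes, 23.1% against 10% by chance.

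At day 11 JQ1 lowered the matrix genes that TAC had raised. Thbs4 (−2.15 ± 0.35), Timp1 (−1.59 ± 0.37), Meox1 (−1.58), Col8a1 (−1.44 ± 0.16), Postn (−1.20 ± 0.24, adjusted p = 0.00107), Tgfb2 (−1.18 ± 0.16), Ccn2 (−1.16 ± 0.19) and Col1a1 (−0.88 ± 0.15) fell, and so did the myeloid genes Clec4a1 (−2.24 ± 0.24), Clec12a (−2.02 ± 0.27), Cd180 (−1.91 ± 0.17), Ms4a7 (−1.86 ± 0.23) and the integrin Itgb6 (−1.84). Hexim1 (1.77 ± 0.12), the adrenaline synthesis gene Pnmt (1.60 ± 0.23), H3c15 (1.42 ± 0.33), Mir1a-1 (1.39), the titin cap gene Tcap (1.30 ± 0.10) and Alas2 (1.09, and 0.61 without JQ1 replicate 3) rose most, with Gclc (0.95 ± 0.10) and Brd2 (0.88 ± 0.08). Myh7 was not called (−0.51 ± 0.22, adjusted p = 0.118), nor were Il6, Myc and Atp2a2 (adjusted p = 0.983, 0.374 and 0.109).

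The remaining stress genes were called at day 11 with all arrays but not without some of them. Nppa (−0.60 ± 0.18, adjusted p = 0.0269) was lost without JQ1 replicate 1 (0.0635) or 3 (0.0924) or vehicle replicate 1 (0.0715), 2 (0.0563) or 3 (0.0699). Nppb (−1.01 ± 0.32, adjusted p = 0.032) was lost without JQ1 replicate 1 (adjusted p = 0.0568) or 3 (−0.58, adjusted p = 0.206) or vehicle replicate 1 (0.0616) or 3 (0.122). Acta1 (−1.07 ± 0.29, adjusted p = 0.0143) was lost without JQ1 replicate 3 (0.0719), and Ankrd1 (−0.28 ± 0.07, adjusted p = 0.0118) without JQ1 replicate 3 (0.0699) or vehicle replicate 3 (0.0568). The rise in Myh6 (0.15 ± 0.05, adjusted p = 0.0443) was lost without JQ1 replicate 1 (0.0922), 2 (0.122) or 3 (0.0919) or vehicle replicate 1 (0.118), 2 (0.0801) or 3 (0.098).

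Matrix groups fell and fuel groups rose with JQ1 at day 11, and of 20 groups called the histone genes alone were kept with an estimated correlation (6 of 9 higher, 6 over the list alone, median 0.52, adjusted p = 0.0431), with H1f2 at 0.79. Matrix genes other than collagens fell in 27 of 40 (35 over the list alone), collagens in 15 of 19 (16), TGF-beta targets in 13 of 21 against 1 higher (14 and 1) and macrophage markers in 16 of 25 (17). Each had adjusted p = 0.137 with an estimated correlation, as had fatty acid genes (20 of 33 higher and 1 lower, 25 and 2), respiratory chain subunits (17 of 61 higher, 30) and BET and P-TEFb genes (5 of 17 higher and 1 lower, 6 and 1). Col15a1 (−1.32), Mfap5 (−1.37), Fstl1 (−0.96), Mpeg1 (−1.35), Plin5 (0.68), Acaa2 (0.37) and Ndufa9 (0.24) are examples. Fetal and stress genes fell in 14 of 25 and rose in 1 (15 and 1, median −0.51, adjusted p = 4.97e-05), Rcan1 by −1.38 and Uck2 by −1.15, genes of the tricarboxylic acid cycle rose in 10 of 22 (12) with Pcx at 0.48, and clock genes in 5 of 16 against 1 lower (5 and 2) with Hlf at 0.81. All 3 had adjusted p = 0.166 with an estimated correlation. Fibroblast markers fell in 7 of 18 (9 and 1 higher, adjusted p = 0.00329, and 0.3 with an estimated correlation), cytokines in 10 of 35 (11, adjusted p = 0.000209, and 0.39) and lymphocyte markers in 2 of 21 (2, adjusted p = 0.0132, and 0.525). Oxidative stress genes rose in 5 of 17 and fell in 1 (7 and 2, adjusted p = 0.00234, and 0.39 with an estimated correlation), Mt2 by 0.94.

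Calls of 5 groups at day 11 depended on single arrays. Interferon-stimulated genes (3 of 23 lower, 5 over the list alone, adjusted p = 0.0119, and 0.619 with an estimated correlation) were lost without JQ1 replicate 3 (0.0985), and adult sarcomere genes (2 of 19 higher, 1, adjusted p = 0.0157, and 0.498) without vehicle replicate 1 (0.0526). Red cell markers (2 of 7 higher, 2, adjusted p = 0.0446, and 0.468 with an estimated correlation) were lost without JQ1 replicate 3 (0.297, mean shift from 0.35 to 0.11) or vehicle replicate 1 (0.071) or 3 (0.0963). Mesothelial markers (3 of 15 lower, 5, adjusted p = 0.0473, and 0.424) were lost without JQ1 replicate 2 (0.0752) or vehicle replicate 2 (0.0739). Glycolysis genes (5 of 20 higher and 2 lower, adjusted p = 0.0493, and 0.424) were lost without JQ1 replicate 2 (0.101, mean shift from 0.04 to 0.02) or vehicle replicate 1 (0.071) or 2 (0.0567). Proliferation genes had 0 called by limma (3 at an unadjusted p under 0.05) with a median of −0.06, and endothelial markers had 4 lower without a group call. JQ1 changed 3180 genes at day 11, 1500 higher and 1680 lower (155 and 425 at 1.5-fold or more). With arrays centred on their median the split was 2334 higher and 1099 lower. The count was 2107 without vehicle replicate 1, 2110 without vehicle replicate 2, 2039 without JQ1 replicate 1 and 2062 without JQ1 replicate 2. Groups did not overlap in 7239 genes, 36.3% against 10% by chance.

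After 28 days JQ1 hearts had lower fibrosis genes, lower cardiomyocyte stress genes and lower vascular markers than vehicle hearts. As groups they were called with the fixed correlation and not with an estimated one. Thbs4 (−2.54 ± 0.35, 5.82-fold lower), the collagen-binding Fmod (−2.45 ± 0.44), Cilp (−2.41 ± 0.28), Clec4a1 (−2.39 ± 0.24), the antigen presentation gene H2-Aa (−2.31 ± 0.38) and Nox4 (−2.26 ± 0.30) fell most. Postn (−1.42 ± 0.24), Acta1 (−1.29 ± 0.29), Tgfb2 (−1.10 ± 0.16), Myh7 (−1.09 ± 0.22, adjusted p = 0.000821), Nppa (−0.93 ± 0.18, adjusted p = 0.000857), Ccn2 (−0.84 ± 0.19), Col1a1 (−0.77 ± 0.15) and Ankrd1 (−0.43 ± 0.07) fell as well. Hexim1 (1.94 ± 0.12), Cd24a (1.31 ± 0.26), the haem synthesis gene Alas2 (1.22), Zswim6 (2.29-fold), H3c4 (1.19 ± 0.26) and Gclc (0.93 ± 0.10) rose. Nppb was not called (−0.75 ± 0.32, adjusted p = 0.0959), nor were Il6, Myc, Myh6 and Atp2a2 (adjusted p = 0.584, 0.0843, 0.293 and 0.996). The chemokine Cxcl2 (1.52) was raised with all arrays, but at 0.34 without JQ1 replicate 3 it was not (adjusted p = 0.0747), nor without vehicle replicate 1 (0.0732), 2 (0.0904) or 3 (0.0786).

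Of the gene groups 13 were called with JQ1 at day 28, and camera called 0 with an estimated correlation (6 at an unadjusted p under 0.05), while fry called 15. Matrix genes other than collagens fell in 30 of 40 (32 and 2 higher over the list alone), collagens in 13 of 19 (13), TGF-beta targets in 11 of 21 (11) and fibroblast markers in 7 of 18 against 1 higher (10 and 2), with Ccn5 (−1.53), Tgfb3 (−1.40), Col14a1 (−1.34) and Loxl1 (−0.71) among them. These had adjusted p = 0.18, 0.261, 0.192 and 0.261 with an estimated correlation. The vehicle arrays compared were uneven on the matrix genes other than collagens, with mean scores of 0.758, 0.209 and 0.905. Endothelial markers fell in 12 of 22 (13, median −0.33, adjusted p = 6.37e-06, and 0.18 with an estimated correlation), including Ptprb (−0.80), Vwf (−0.71), Tie1 (−0.46) and Mmrn2 (−0.46). Smooth muscle and pericyte markers fell in 7 of 16 (8 and 1 higher, adjusted p = 0.0232, and 0.262 with an estimated correlation), Tagln by −0.55 and Pdgfrb by −0.35, lost without JQ1 replicate 3 (0.0855) or vehicle replicate 1 (0.0706). Macrophage markers fell in 11 of 25 (16 and 1 higher, adjusted p = 3.79e-07, and 0.213 with an estimated correlation), Ms4a7 by −2.14, and fetal and stress genes in 12 of 25 against 1 higher (14 and 2, adjusted p = 0.000622, and 0.262). Angiogenic ligands fell in 10 of 27 and rose in 2 (14 and 3, adjusted p = 0.000532, and 0.18 with an estimated correlation), Igf1 by −1.21 and Edn1 by −0.52, and renin-angiotensin, adrenergic and natriuretic genes in 5 of 20 against 2 (9 and 2, adjusted p = 0.00783, and 0.25), Ace by −0.72 and Npr3 by −0.75. Red cell markers rose in 4 of 7 (5, adjusted p = 0.0029, and 0.266 with an estimated correlation) and histone genes in 5 of 9 (7, adjusted p = 0.00262, and 0.18), with Tspo2 at 0.50 and H2bc4 at 0.60. Genes of the tricarboxylic acid cycle rose in 8 of 22 (8, adjusted p = 0.0047, and 0.627 with an estimated correlation), lost without JQ1 replicate 3 (0.0671).

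JQ1 changed 3907 genes at day 28, 1427 higher and 2480 lower, and at 1.5-fold or more 84 higher and 655 lower. With arrays centred on their median the split was 2700 higher and 2106 lower. Fitted with only the 2 groups compared, 2126 genes were called. Groups did not overlap in 6986 genes, 35% against 10% by chance. Fatty acid genes were not called as a group (7 higher and 4 lower), nor were proliferation genes (1 and 1) or BET and P-TEFb genes (6 and 1, adjusted p = 0.0926).

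**Figure D2:**
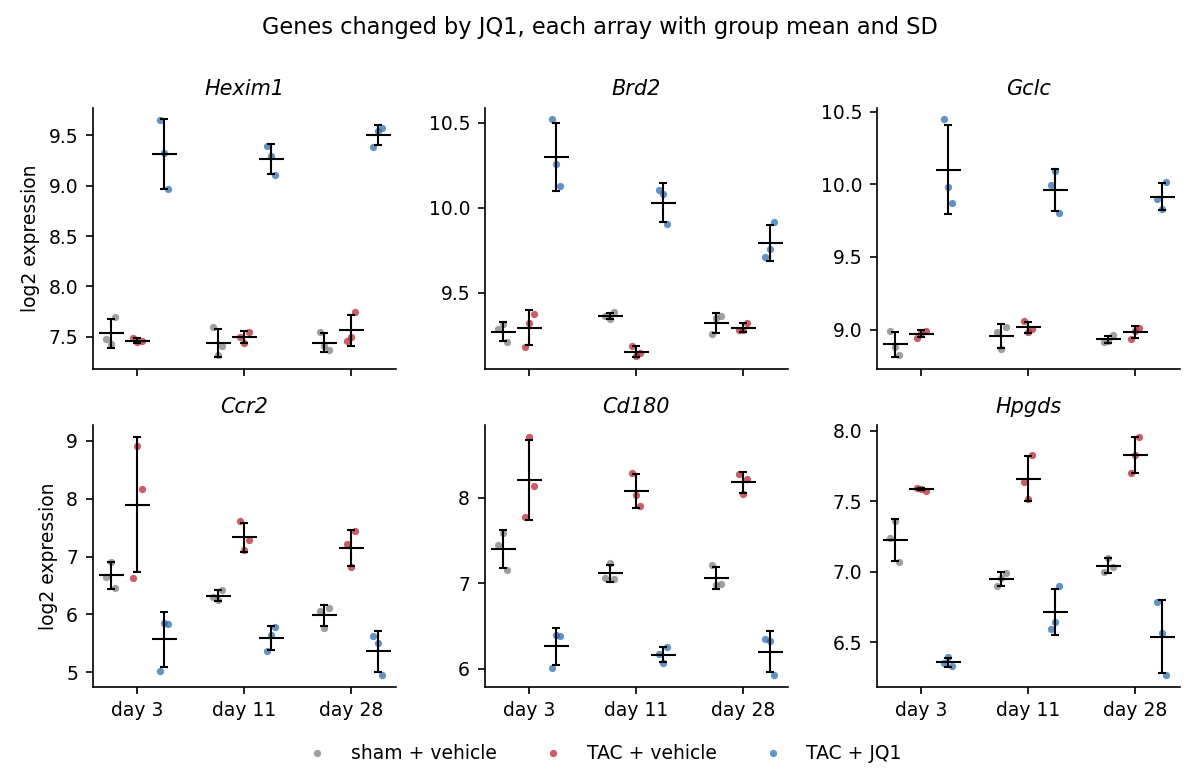
Log2 levels of Hexim1, Brd2, Gclc, Ccr2, Cd180 and Hpgds in sham vehicle, TAC vehicle and TAC JQ1 hearts at days 3, 11 and 28. Each point is 1 array, with n = 3 per group.

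Averaged over the 3 days (n = 9 arrays per arm), the TAC rises with the smallest p included Postn (2.81 ± 0.14, adjusted p = 1.41e-12) and the membrane protein gene Emp1 (1.40 ± 0.07), beside Acta1 (1.89 ± 0.17), Myh7 (1.87 ± 0.13), Nppb (1.78 ± 0.18), Nppa (1.65 ± 0.11), Ccn2 (1.56 ± 0.11), Tgfb2 (1.05 ± 0.09), Col1a1 (0.98 ± 0.09), Il6 (0.74 ± 0.12), Ankrd1 (0.73 ± 0.04) and Myc (0.52 ± 0.09). Phkg1 (−1.17), the interleukin gene Il15 (−0.88), Mylk3 (−0.68) and Gcdh (−0.62) were among the falls with the smallest p, and Atp2a2 (−0.15 ± 0.03) and Myh6 (−0.14 ± 0.03) fell slightly. In all 5172 genes were called, 2594 higher and 2578 lower, or 2203 and 3170 with arrays centred on their median. Singly by day, 347 rose and 297 fell at all 3 days, against 5.34 and 3.59 expected if the days were independent. Of 35 gene groups 16 were called for the averaged TAC effect, 9 of them with an estimated correlation.

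For JQ1 the averaged effect rested on Hexim1 (1.85 ± 0.07, adjusted p = 3.15e-14), Zswim6 (1.21), the magnesium transport gene Cnnm4 (0.89) and the nucleolar gene Nop56 (0.72) upward. Downward it rested on Cd180 (−1.95), the prostaglandin D synthase Hpgds (−1.16), Nxpe4 (−1.12), the chromatin reader Zmynd8 (−0.99), Sh3rf2 (−0.98) and C1qtnf1 (−0.74). Postn (−1.02 ± 0.14), Tgfb2 (−0.95 ± 0.09), Acta1 (−0.80 ± 0.17), Nppb (−0.73 ± 0.18, adjusted p = 0.00318), Col1a1 (−0.70 ± 0.09), Ccn2 (−0.70 ± 0.11), Nppa (−0.58 ± 0.11), Myh7 (−0.43 ± 0.13) and Ankrd1 (−0.28 ± 0.04) fell, while Myc and Atp2a2 were not called (adjusted p = 0.0607 and 0.331). Il6 fell by 0.36 ± 0.12 (adjusted p = 0.0214), lost without day 3 JQ1 replicate 1 (0.0522), day 3 vehicle replicate 2 (0.0567), day 11 vehicle replicate 3 (0.0566) or day 28 vehicle replicate 3 (0.0574). Myh6 rose by 0.08 ± 0.03 (adjusted p = 0.039), a call lost on leaving out JQ1 arrays of day 3 (replicates 2 and 3, 0.061 and 0.0713), day 11 (1, 2 and 3, 0.0532, 0.0646 and 0.0596) or day 28 (2 and 3, 0.0724 and 0.0733), or vehicle arrays of day 3 (2 and 3, 0.0725 and 0.0537), day 11 (1 and 3, 0.0653 and 0.0642) or day 28 (1 and 3, 0.0553 and 0.0743). JQ1 changed 5806 genes on average, 2456 higher and 3350 lower, or 4644 higher and 2540 lower with arrays centred on their median. As gene groups, 18 of 35 were called for the averaged JQ1 effect, 0 by camera with an estimated correlation (7 at an unadjusted p under 0.05) and 23 by fry. Singly by day, 274 genes rose and 664 fell at all 3 days, against 4.6 and 15.9 expected if the days were independent.

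Compared with sham hearts, hearts with TAC and JQ1 still had high Postn (1.79 ± 0.14), Myh7 (1.44 ± 0.13), Acta1 (1.09 ± 0.17), Nppa (1.07 ± 0.11), Nppb (1.05 ± 0.18), Ccn2 (0.86 ± 0.11), Ankrd1 (0.45 ± 0.04), Il6 (0.38 ± 0.12), Myc (0.29 ± 0.09) and Col1a1 (0.28 ± 0.09), and lower Atp2a2 (−0.10 ± 0.03). Tgfb2 (0.10 ± 0.09, adjusted p = 0.517) and Myh6 (adjusted p = 0.116) were not called. Hexim1 (1.89 ± 0.07), Zswim6 (1.45), Gclc (1.06), H2ax (1.02) and Nop56 (0.83) were the rises over sham with the smallest p, and Sh3rf2 (−1.22), Kcnj5 (−1.11), Ppfibp2 (−1.10), Zmynd8 (−1.09), the lipid phosphatase Synj2 (−1.08) and Gramd1b (−0.98) the falls. This comparison called 5954 genes, 2545 higher and 3409 lower, or 3106 and 2713 with arrays centred on their median. Of the 2594 genes higher with TAC 1044 were also called above sham under JQ1 and 284 below it. Of the 2578 lower with TAC 1482 were called below sham and 104 above it. Both comparisons use the same sham arrays, which alone favours the same direction.

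Whether JQ1 opposed TAC was tested on genes chosen from other days, because within a day both effects share the TAC vehicle arrays. For each day, the 200 genes that rose most firmly with TAC on the other days and the 200 that fell were followed. The risen genes had JQ1 medians of −0.25 at day 3 (fry adjusted p = 0.000834), −0.54 at day 11 (adjusted p = 2.83e-06) and −0.40 at day 28 (adjusted p = 3.37e-05), with 71, 154 and 119 of 200 called lower and 2, 1 and 1 called higher. By camera with an estimated correlation the adjusted p was 0.0641, 0.0317 and 0.0429. Genes that fell with TAC were higher with JQ1 at day 11 (median 0.26, fry adjusted p = 3.37e-05, and 0.0356 by camera with an estimated correlation), where 111 of 200 were called. At day 3 (median 0.01, adjusted p = 0.818) and day 28 (median 0.06, adjusted p = 0.523) they were not. At day 11 the potassium channel gene Kcnj3 fell by 1.23 with TAC and was higher by 0.96 with JQ1, but both values use the TAC vehicle arrays of that day. Within days, 285, 790 and 868 genes were called higher with TAC and lower with JQ1 at days 3, 11 and 28, against 64.1, 131 and 202 expected from the counts alone, and 52, 640 and 234 lower and then higher, against 28.4, 116 and 99.6. The shared arrays alone would give a correlation between both effects over genes of −0.501, −0.499 and −0.497 in simulated data without effects, and those observed were −0.312, −0.624 and −0.539. Real effects add to the spread of both, so these correlations cannot be compared directly. The covariances observed were −0.0151, −0.0384 and −0.0388, against −0.00653, −0.00652 and −0.00648 in the simulated data.

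**Figure D3:**
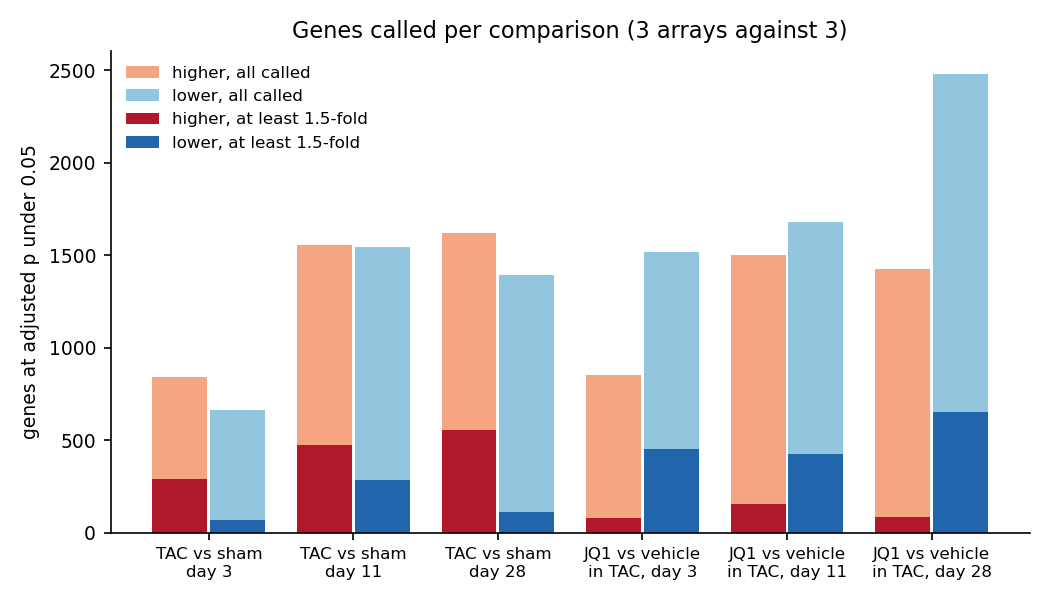
Number of genes called higher and lower at adjusted p under 0.05 for TAC vs sham and for JQ1 vs vehicle in TAC hearts, at days 3, 11 and 28, with n = 3 arrays per group.

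The TAC effect differed between days in 261 genes. Late-rising genes led: the fibroblast peptidase inhibitor Pi16 (0.08, 0.97 and 1.44 at days 3, 11 and 28, each ± 0.12, adjusted p = 0.0024), Timp2 (0.05, 0.51 and 0.81, adjusted p = 0.00247), the complement regulator Serping1 (−0.08, 0.33 and 1.08, adjusted p = 0.00388) and the protease Htra4 (−0.26, 0.39 and 1.22, adjusted p = 0.00247). The muscle kinase Speg went the other way (0.16, −0.19 and −0.74, adjusted p = 0.00344), and Trmt112 was lowest in between (−0.09, −0.46 and 0.46, adjusted p = 0.00388). The probe sets of Trmt112 disagreed at day 28. One that was not used gave 0.03, −0.32 and −0.07, and another −0.04, −0.37 and 0.46. As groups, the TAC effect on the unfolded protein response was lower at day 11 than at day 3 (median difference −0.29, 8 members lower, camera adjusted p = 0.00447 with an estimated correlation). More of this came from sham hearts, whose mean score rose from −0.0962 to 0.141, than from TAC hearts, where it fell from 0.106 to −0.0313. The effect on fibroblast markers was higher at day 28 than at day 3 (median difference 0.61, 6 members higher, adjusted p = 0.0175 with an estimated correlation). Hspa5 (adjusted p = 0.0123), Hyou1 (0.00864) and Manf (0.0096) differed singly, whereas for Nppa, Nppb, Myh7 and Postn a difference between days was not called (adjusted p = 0.726, 0.657, 0.968 and 0.211). Between days 3 and 28 the TAC effect differed in 319 genes, 205 with a higher and 114 with a lower effect at day 28. The count of 261 became 405 without day 28 TAC vehicle replicate 2 and 108 without replicate 3, and 108 without day 3 TAC vehicle replicate 3. Without day 11 TAC vehicle replicate 2 or 3 it was 160 or 168, without sham replicate 1 or 3 of day 3 114 or 140, without sham replicate 1 or 3 of day 11 140 or 164, and without sham replicate 1, 2 or 3 of day 28 109, 96 or 158.

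The JQ1 effect differed between days in 213 genes (44 with the replicate number as a block, against 135 for TAC), and most of those with the lowest p were lower at day 28. Vwf, the endothelial clotting glycoprotein, changed by 0.05, −0.05 and −0.71 at days 3, 11 and 28 (each ± 0.09, adjusted p = 0.00942). The lipoprotein receptor Lrp1 changed by −0.01, −0.39 and −0.79 (adjusted p = 0.00728), the neuron navigator Nav1 by −0.08, −0.47 and −0.89 (adjusted p = 0.00309), Tspan17 by −0.05, −0.39 and −0.76 (adjusted p = 0.00309) and Ttc28 by −0.10, −0.20 and −0.86 (adjusted p = 0.00109). Arhgap32 was lower at days 3 and 28 but not between (−0.28, 0.01 and −0.62, adjusted p = 0.00814). Mki67 (adjusted p = 0.0485), Cilp (0.0269) and Col8a1 (0.027) differed too. For Myh7 the difference between days was not called (adjusted p = 0.052), nor for Ccn2 (0.0806), Nppa (0.225), Acta1 (0.162) or Postn (0.178), so a later start of the JQ1 effect on these genes was not shown. The count of 213 became 437 without day 28 JQ1 replicate 3, 57 and 83 without replicates 1 and 2 of that group, 37 without day 28 vehicle replicate 1, 87 without day 3 vehicle replicate 3, 75, 53 and 60 without day 11 vehicle replicates 1, 2 and 3, and 59 and 47 without day 11 JQ1 replicates 1 and 2.

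Sham hearts themselves differed between days in 13 genes, and with the replicate number as a block in 0 by limma (1289 at an unadjusted p under 0.05). Relative to day 3, the orphan receptor Nr4a3 was higher at days 11 and 28 (0.98 and 1.07, each ± 0.17), Hspg2 (0.16 and 0.58) and Kmt2d (0.14 and 0.51) were higher at day 28 and Snora52 was lower (−0.60). The stress genes Creld2 (0.56 and 0.02) and Xbp1 (0.40 and −0.03) were higher at day 11. All 6 had adjusted p = 0.0162. The limma count was 0 without sham replicate 1 of day 3 or replicate 2 or 3 of day 28 (1336, 991 and 1092 genes at an unadjusted p under 0.05), 5 without replicate 3 of day 3 and 8 without replicate 3 of day 11.

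**Figure D4:**
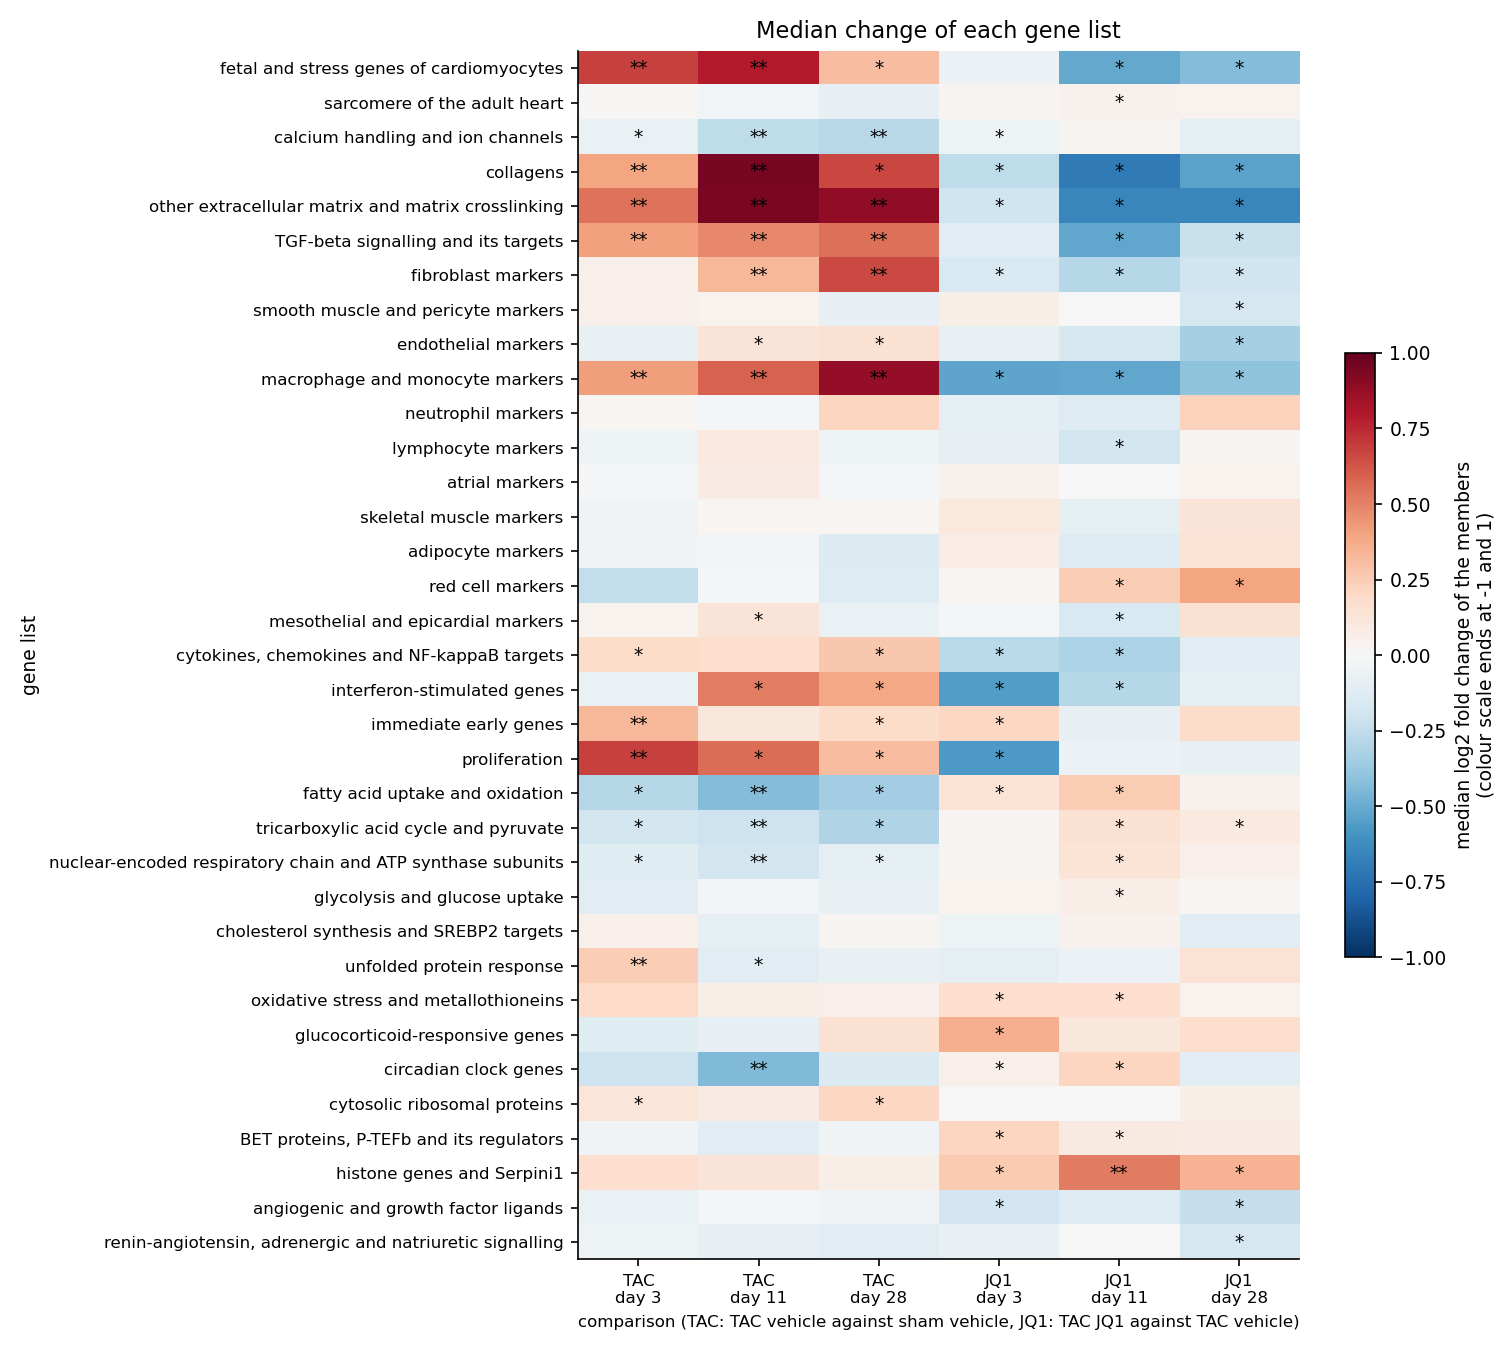
Median log2 fold change of the members of each gene list for TAC vs sham and JQ1 vs vehicle in TAC hearts at days 3, 11 and 28. One star marks camera adjusted p under 0.05 and a pair of stars marks lists also called with an estimated correlation.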

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

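All splits of the arrays and the tests between days described here were planned, while leaving out single arrays in the tests between days was chosen after the result was seen. The TAC effect differed between days in 261 genes by a moderated F test of the difference itself. Among them were Pi16 (adjusted p = 0.0024), Htra4 (0.00247), Timp2 (0.00247), Speg (0.00344), Trmt112 (0.00388) and Serping1 (0.00388), and 36 more of the genes named by the rule. For Trmt112 the probe sets disagreed at day 28, where one that was not used gave −0.07. Pi16, Htra4, Timp2 and Serping1 had their highest effect at day 28, where matrix and fibroblast genes were also high. Of 100 exchanges of days among the arrays of each arm, the real one included, 1 gave as many genes, the real one, and the highest other gave 13. Days were exchanged in each arm by itself, which also breaks differences between days that both arms share. The share under 0.05 therefore cannot exclude chance for the TAC effect alone.

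The JQ1 effect differed between days in 213 genes, among them Ttc28 (adjusted p = 0.00109), Nav1 (0.00309), Tspan17 (0.00309), Lrp1 (0.00728), Arhgap32 (0.00814) and Vwf (0.00942), and 31 more of the genes named by the rule. Here 3 of 100 exchanges of days gave as many genes, and the highest other gave 279, so the share is under 0.05 but single arrangements of the arrays exceeded the real count. Sham hearts differed between days in 13 genes. Of 100 exchanges 1 gave as many, the real one, and the highest other gave 7. These exchanges do not keep replicate numbers together. For JQ1, as for TAC, they also break differences between days that both arms share, so they do not test the JQ1 effect alone. With the replicate number as a block the counts were 135 (TAC), 44 (JQ1) and 0 (sham, 1289 genes at an unadjusted p under 0.05 in limma), so the call of the sham genes was lost.

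As gene groups, the TAC effect differed between days for 15 lists between days 3 and 11, 13 between days 3 and 28 and 13 between days 11 and 28 with the fixed correlation. With an estimated correlation it differed for the unfolded protein response between days 3 and 11 (adjusted p = 0.00447) and for fibroblast markers between days 3 and 28 (adjusted p = 0.0175). For the unfolded protein response the larger part was a rise in sham hearts (−0.0962 to 0.141), against a fall in TAC hearts (0.106 to −0.0313). Between days 11 and 28 camera called 0 (3 at an unadjusted p under 0.05, 0 by fry). The JQ1 effect differed for 13 lists between days 3 and 11, 22 between days 3 and 28 and 9 between days 11 and 28, of which camera called 0 with an estimated correlation (6, 7 and 2 at an unadjusted p under 0.05, and 0, 3 and 3 by fry).

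Probe sets outside the gene tests also responded. Of 11799 probe sets with no gene listed 800 were called for TAC on the mean of the days (360 higher and 440 lower) and 1123 for JQ1 (827 higher and 296 lower). Of 1321 that list several genes 223 were called for TAC (177 higher and 46 lower) and 238 for JQ1 (155 higher and 83 lower). What these probe sets measure is not given in the sources used here.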

How the results depend on the processing

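The range covariate, and leaving out single arrays in the tests between days, were chosen after the results were seen, and the other alternatives were planned. No named gene or list that was called changed direction under any of them. Splits of the counts into higher and lower genes did turn, as the next paragraph gives. Of 1103 named results 1001 were called, and 722 of these kept their call under every alternative. Of 280 list results 129 were called and 34 kept their call. In the opposition test the 3 sets of risen genes and the fallen genes of day 11 were called by fry under each alternative run, and the fallen genes of days 3 and 28 under none. Median centring, the mean of a gene's probe sets, trend and robust options and the fit to only the 2 groups compared were not run for this test. By camera with an estimated correlation the risen genes of day 3 were not called (adjusted p = 0.0641). Directions were kept except for fallen genes at day 3, which had a median between −0.06 and 0 with sets of 100, the replicate block, or without TAC vehicle replicate 2 or JQ1 replicate 2. Median centring moved the median of all genes by at most 0.07 (JQ1 at day 11).

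With arrays centred on their median the larger of the higher and lower counts became the smaller in each comparison of TAC or JQ1 except TAC at day 3. For TAC the split went from 1555 and 1542 to 1246 and 1733 at day 11, from 1621 and 1392 to 1348 and 1739 at day 28, and from 2594 and 2578 to 2203 and 3170 on the mean of days. For JQ1 it went from 854 and 1518 to 1224 and 1042 at day 3, from 1500 and 1680 to 2334 and 1099 at day 11, from 1427 and 2480 to 2700 and 2106 at day 28, and from 2456 and 3350 to 4644 and 2540 on the mean of days. For TAC JQ1 against sham it went from 2545 and 3409 to 3106 and 2713. Quantile normalization again turned TAC at day 28 (1538 and 1802), as did the range covariate (1728 and 1782), and leaving out the dimmest genes turned JQ1 at day 11 (1786 and 1702). The nearly even splits of TAC at day 11 and on the mean of days turned under further settings. At day 11 these were the dimmest genes left out, trend and robust options, array weights, and leaving out sham replicate 1 or 2 or TAC vehicle replicate 3. On the mean of days they were the same settings of the fit, quantile normalization again and the range covariate, and leaving out sham replicate 2 or 3 of day 3, sham replicate 2 or TAC vehicle replicate 3 of day 11 or sham replicate 1 of day 28. With array weights, or with only the 2 groups compared, JQ1 called more genes at day 11 (6933 and 3236) than at day 28 (3874 and 2126), while as deposited day 28 had more.

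Counts that moved more than 1.5 times were these, and the cause was not tested. With array weights TAC gave 2902 genes at day 3 and 5974 at day 11, JQ1 gave 6933 at day 11, and the tests between days gave 2045 (TAC), 2710 (JQ1) and 2164 (sham). Fitted with only the 2 groups compared, TAC gave 250 at day 3, and JQ1 422 at day 3 and 2126 at day 28. The same fit left TAC at days 11 and 28 (3082 and 3081) and JQ1 at day 11 (3236) close to the main counts. Those main counts were 3097, 3013 and 3180, so fewer arrays alone do not account for the drops. At 1.5-fold or more, TAC gave 357, 759 and 669 at days 3, 11 and 28, JQ1 534, 580 and 739, the means over days 471 (TAC), 493 (JQ1) and 444 (TAC JQ1 against sham), and the tests between days 163, 118 and 5. With the dimmest genes left out the tests between days gave 580 (TAC), 469 (JQ1) and 21 (sham). With trend and robust options they gave 498 (TAC) and 358 (JQ1), and with the range covariate 679 (TAC) and 21 (sham).

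Replicate numbers were not taken as pairs, because in no comparison were all 3 correlations between same-numbered arrays over 0.1. The correlations ran from −0.462 to 0.5. They were over 0.1 in 2 of 3 pairs for sham and TAC vehicle at day 11 and again at day 28, where all 3 sham arrays correlated best with their own number, in 1 of 3 for TAC vehicle and JQ1 at day 28, and in 0 of 3 for the other comparisons. Pairing at days 11 and 28 is thus not excluded. With the number as a block the tests between days gave 135 (TAC), 44 (JQ1) and 0 (sham, 1289 genes at an unadjusted p under 0.05 in limma).

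Leaving out single arrays, TAC gave 466 to 1812 genes at day 3 and 1794 to 2817 at day 28, JQ1 1409 to 2740 at day 3 and 2039 to 2679 at day 11, and the tests between days 96 to 405 (TAC), 37 to 437 (JQ1) and 0 to 15 (sham). The lowest and highest TAC counts between days came without sham replicate 2 and TAC vehicle replicate 2 of day 28.

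Gene lists depended most on the correlation assumed. With an estimated correlation camera called 8 at day 3 and 5 at day 28 for TAC, 9 for TAC on the mean of days, 1 for JQ1 at day 11, and 0 for JQ1 at day 3, at day 28 and on the mean of days (6, 6 and 7 at an unadjusted p under 0.05, and 12, 15 and 23 by fry). The estimate is itself made from residuals with 18 degrees of freedom.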

Other observations

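The tests on macrophage markers and on the opposition of JQ1 to TAC, and the array range as a covariate, were chosen after the results were seen, and the other tests in this part were planned. Some signalling genes moved with TAC, with JQ1 or with both. Igf1, a growth factor of cardiac macrophages and fibroblasts, rose with TAC at all 3 days (0.83 ± 0.17, 1.27 ± 0.17 and 1.26 ± 0.17) and fell with JQ1 at all 3 (−0.90 ± 0.17, −1.23 ± 0.17 and −1.21 ± 0.17, n = 3 arrays per group). Hgf fell with JQ1 by 0.69 ± 0.07 on the mean of days, and Nrg1 (−0.77 ± 0.15) and Edn1 (−0.52 ± 0.09) at day 28. The angiotensin-converting enzyme gene Ace rose with TAC (0.40, 0.98 and 0.84 at days 3, 11 and 28) and fell with JQ1 at days 11 (−0.57 ± 0.09) and 28 (−0.72 ± 0.09).

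Other genes followed no single pattern. The potassium channel gene Kcnj5 fell with TAC (−0.61 ± 0.04 on the mean of days) and fell further with JQ1 (−0.50 ± 0.04). The titin cap gene Tcap fell with TAC by 0.48 ± 0.06 and rose with JQ1 by 0.87 ± 0.06, most at day 11. The clock repressor Cry1 rose with JQ1 at each day (0.69, 0.51 and 0.47), while Nr1d1 fell at day 28 (−1.18 ± 0.14) with a difference between days (adjusted p = 0.0173 in limma). The time of day at which hearts were taken is not given in the sources used here. Slow troponin T, Tnnt1, rose with JQ1 by 0.65 ± 0.06.

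Single arrays stood out within some lists (mean score relative to all arrays). Proliferation genes scored 0.857 in TAC vehicle replicate 2 of day 3 against 0.13 and 0.259 in the other two, and collagens −0.297 in JQ1 replicate 1 of day 3 against 0.0584 and 0.184. Interferon-stimulated genes scored 0.907 in JQ1 replicate 1 of day 28 against −0.0787 and −0.112 in the other two. Neutrophil markers and cytokines scored 0.673 and 0.625 in JQ1 replicate 3 of day 28, and red cell markers 0.766 in JQ1 replicate 3 of day 11. In TAC vehicle replicate 2 of day 28 matrix genes other than collagens scored 0.209 and collagens 0.0649. The other arrays of that group had 0.758 and 0.905, and 0.443 and 0.47. Markers of neutrophils, atrium, skeletal muscle and adipocytes and genes of cholesterol synthesis were called in none of the comparisons with sham or vehicle by camera, within days or on the mean of days. Glycolysis genes were mixed with TAC, 2 higher and 7 lower of 20 at day 28.

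At day 28 JQ1 gave more lower than higher genes, 63.5% of those called. JQ1 arrays of that day had a narrower range (mean interquartile range 2.43, SD 0.155) than vehicle arrays (2.62, SD 0.0775). With the range as a covariate, which was chosen after the results were seen, 57.3% were lower, between the bounds set for this test. With genes divided by mean level into 3 equal parts, 31.3% of called genes were lower in the dimmest part, against 72.4% in the middle and 65.7% in the brightest, so a compression of bright genes may be part of the pattern. Quantile normalization again gave 61.5%, which passed the bound set beforehand, but that bound named only this scaling: median centring gave 43.8%, so the scaling cannot be told apart from a biological excess. Genes changed at least 1.5-fold were lower far more often under all of these (84 higher and 655 lower as deposited, 155 and 601, 84 and 635, and 104 and 570).

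Macrophage and monocyte markers had a median of −0.47 with JQ1 on the mean of days. An even loss of all macrophages would lower the well expressed markers alike, but over the 9 of 25 with a mean of at least 9.34 in TAC vehicle hearts the SD of the effect was 4.22 times their median standard error. Lyve1, which lymphatic vessels also express, carries this: without it the SD was 2.59 times, between the bounds set, so an even loss stays open. Cd68 fell by 0.72, Cybb by 0.65, Mrc1 by 0.55, Csf1r by 0.45, Lyz2 by 0.40, C1qb by 0.37 and C1qc by 0.36, C1qa was not called (−0.13) and Lyve1 rose by 0.30. A smaller share of all non-muscle cells stays open too: the endothelial median was 0.339 and the smooth muscle median 0.129 of the macrophage median. A change in which macrophages are present, or in their transcription, may underlie the pattern and was not tested.

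Genes that rose with TAC were lower with JQ1. The TAC vehicle arrays shared within a day would leave a median near 0 for genes chosen on other days, and the one nearest 0 was −0.247. A smaller share of non-muscle cells would by itself spare cardiomyocyte genes, but the fetal and stress list had medians of −0.508 at day 11 and −0.434 at day 28. Such a share alone would therefore not account for the fall of this list at these days, as far as its members are expressed in cardiomyocytes only. The fall was known before this test was chosen, so the test could not have come out otherwise. Whether such a share contributed to the fall of the other risen genes cannot be decided from this list, because both can happen together. At day 3 the median of the list was −0.0564, with 3 genes higher and 1 lower, so there a smaller share of these cells stays open for this list too. For genes that fell with TAC the medians on the held-out day were 0.259 at day 11, which shared arrays cannot give, but 0.00638 at day 3 and 0.0631 at day 28, with fry adjusted p = 0.818 and 0.523. At these days the shared arrays are not excluded. The median at day 28 lay above the 0.03 that simulated data without effects reached. Genes were independent in the simulation but had an estimated correlation of 0.308 in this set, so this decides nothing. A smaller share of non-muscle cells would raise cardiomyocyte genes alike at day 11. Over the fetal and stress, sarcomere and calcium handling lists the highest upper quartile was 0.184, under the 0.259 of the fallen genes. This comparison carries little weight, because the fallen genes were chosen for extreme TAC effects and the lists were not. The fetal and stress list was also already known to fall with JQ1. A partial reversal of the TAC response by JQ1 is a hypothesis for risen genes at days 11 and 28 and for fallen genes at day 11. A smaller share of non-muscle cells as a part of the pattern is not excluded, and counts of cell types in such hearts would test it.

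Splits of the arrays were counted for each comparison. For 3 against 3 arrays the 10 splits are too few for a share under 0.05: in each comparison 1 split, the real one, gave as many genes. The real count and the highest other were 1506 and 1, 3097 and 0, and 3013 and 0 for TAC at days 3, 11 and 28, and 2372 and 13, 3180 and 0, and 3907 and 4 for JQ1. For the means over days 100 splits within days were drawn, and 1, the real one, gave as many genes in each case, so chance is excluded at a share under 0.05. The highest others were 3132 against 5172 for TAC, 1896 against 5806 for JQ1 and 933 against 5954 for TAC JQ1 against sham, and some of these splits keep the real groups on 2 of the 3 days.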
